A study of Mus musculus with 6 samples.

How the data were processed

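RNA was measured by sequencing in 6 libraries of J1 mouse embryonic stem cells. The cells came from 3 lines: the unmodified wild-type line, a line with a scramble short hairpin RNA (shRNA), and a line with an shRNA against Carm1. Each line was sampled once after 48 h with the ethanol vehicle and once after 48 h with 1 µM retinoic acid (RA), per the labels' protocols. The cells grew on gelatin in medium with the cytokine LIF, and the libraries were read as single-end 51-nucleotide reads on a HiSeq 2500. Groups were taken from the labelled genotype and treatment. There was 1 library per line and treatment, and nothing in the labels describes replicate cultures, so p-values measure only the spread between these libraries.

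The deposited values are FPKM, that is reads scaled to transcript length and library depth, which the authors made with TopHat2 and Cufflinks on genome build mm9, per the submitters' processing notes. The versions of these tools are not given in the sources used here. Header notes in the deposited workbook call the same values RPKM. Whether the authors scaled the libraries against each other is not given in the sources used here. The deposited table held 20793 rows with 20462 distinct gene symbols, and a status word from Cufflinks stood beside each value. A copy of the table held the same values (0 differed), and the workbook's other sheets were sorted copies and were not used.

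The 2 rows with a failed estimate in at least 1 library (Zmynd8 and Ddx19b) were left out, since a failed estimate is listed at 0. Where a symbol was repeated (519 rows), the row with the highest mean was kept, which left 20460 genes. Genes with a mean of at least 1 FPKM over the 6 libraries were tested (11227 genes), on the scale log2(FPKM + 1). Fold changes on this scale understate the change of low genes. Coordinates are those of the deposited table, with 1 added to each start because the table counts from 0.

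The RA response was fitted with limma 3.58.1 in R 4.3.3 as line plus treatment, with 2 residual degrees of freedom before moderation, and p-values were adjusted by the Benjamini-Hochberg method over all genes tested (threshold 0.05). The line is the block, because the wild-type, scramble and Carm1 shRNA lines were each measured under both treatments. The same fit gave the contrasts between lines. These compare the lines measured here only, since each shRNA was represented by 1 line. A model with an interaction between treatment and the Carm1 shRNA line had 1 residual degree of freedom. Comparisons of the Carm1 shRNA line with both control lines under a given treatment were planned without a test. They count genes that differed at least 2-fold from both controls in the same direction, and the same count with the scramble or the wild-type line in that place is the yardstick. A contrast of the Carm1 shRNA line with the mean of the control lines within each treatment, from the interaction model, was added after seeing the data. Its differences are given without a p-value or a count of genes, since each treatment had 1 Carm1 shRNA library.

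The gene lists (18 lists), the rule for named genes, the tests and most alternatives were fixed before the data were examined. The lists cover naive and formative pluripotency, retinoid metabolism, Hox clusters, neural cells, extraembryonic endoderm, mesendoderm, trophoblast and keratins, the two-cell-like state, arginine methyltransferases, nuclear receptor coregulators, fibroblasts and feeder cells, interferon, p53 and stress, proliferation, glycolysis and hypoxia, imprinted genes, and LIF, BMP and WNT targets. Lists were tested for the RA response with camera (limma) at a preset inter-gene correlation of 0.01, and again with an estimated correlation. The estimated form also tests at the 2 residual degrees of freedom of the fit, which by itself raises its p-values. For the Carm1 shRNA comparisons, a list's median difference was placed among 10000 random lists of the same size, matched on mean expression in 20 bins. Named RA genes were the 12 higher and 12 lower genes past the threshold with the same sign in all 3 lines, ranked by the smallest response over the lines. Named genes of the other comparisons were up to 10 higher and 10 lower genes at least 2-fold from both controls, ranked by the smaller difference, with up to 5 more per direction for calls shared by both treatments. Carm1 and members of the lists could always be named. Clone names, accessions and small RNAs were counted but not named, and some genes that the rule names are not reported here.

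The total per library was 505266 to 537592 FPKM, and 10632 to 11519 genes reached 1 FPKM. FPKM carry no read counts. The smallest values of a gene step by what 1 read is worth, and with transcript lengths from the GENCODE mouse annotation the most common step put the depth near 25200000 reads in the scramble vehicle library and between 30500000 and 34200000 reads in the other 5. The value of 1 read relative to the wild-type vehicle library scattered by 0.0833 (robust SD over 129 genes) in the scramble vehicle library and by 0.00733 to 0.022 in the other 4. These depths are estimates, so no interval or floor was derived from them.

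The fits were tested on simulated data for all 11227 genes with known changes in 100 genes per fold size. The noise of each gene was its residual spread in the fit of line plus treatment, which includes any real difference of response between lines. For the RA contrast 78% of 2-fold and 94% of 4-fold changes were recovered. For the contrast of the Carm1 shRNA and scramble lines 64% and 92% were recovered. For the interaction 0 of 100 genes were recovered at either size, while the count by size found 31% of 2-fold and 99% of 4-fold differences of response and also called 48 unchanged genes. The added contrast recovered 0 of 100 genes at either size with vehicle, and with RA 3 of 200 2-fold and 151 of 200 4-fold differences. More genes were changed with RA, and the adjusted threshold depends on that number, so this gap says nothing about the treatments. Far fewer genes were changed than the 7141 called for RA in the data, so the rates above are not the power in these data. The alternatives were other pseudocounts, filters, scalings, fold thresholds, control lines and gene choices, limma's trend, the fit without the line term, leaving out each line, and summed repeated symbols. Keeping the failed rows and leaving out rows marked as low data were added after seeing the data. Figures were drawn with matplotlib 3.10.9.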

Results

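Gene expression was measured by RNA sequencing in J1 mouse embryonic stem cells, to examine the part of the arginine methyltransferase CARM1 in the response to retinoic acid (RA), a vitamin A derivative that drives these cells out of pluripotency. The 6 libraries comprised the wild-type line, a line with a scramble short hairpin RNA (shRNA) and a line with an shRNA against Carm1, each after 48 h with vehicle or with 1 µM RA. Every combination of line and treatment was represented by 1 library, so values are given per library and no replicate error within a group exists. The deposited FPKM values summed to 505266 to 537592 per library, and the step size of low values put the depth between 25200000 and 34200000 reads.

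Carm1 itself was lower in the line with the Carm1 shRNA. Carm1 (chromosome 9, 21351338 to 21393909, build mm9) stood at 8.49 FPKM with vehicle and 6.73 FPKM with RA in that line, against 36.1 and 29.9 FPKM in the scramble line and 37.0 and 29.5 FPKM in the wild-type line. These levels were 23.5% and 22.6% of those in the scramble line under the same treatment. The difference between the Carm1 shRNA and scramble lines was -1.98 ± 0.07 (SE) on the log2(FPKM + 1) scale (limma, adjusted p = 0.0106), and Carm1 was lower in 2 of 2 treatments. This call ended without a filter on low values and after quantile normalization, where 0 genes passed in this contrast. Other arginine methyltransferases did not share this difference. Prmt1 was 396 FPKM in the Carm1 shRNA line and 390 FPKM in the scramble line with vehicle, and Prmt5 was 120 and 118 FPKM. Yipf2, whose annotated span overlaps that of Carm1 by 784 bases, was 10.1 FPKM with vehicle in the Carm1 shRNA line and 25.9 FPKM in the scramble line. Reads in the overlap cannot be assigned to a gene without strand.

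**Figure D1:**
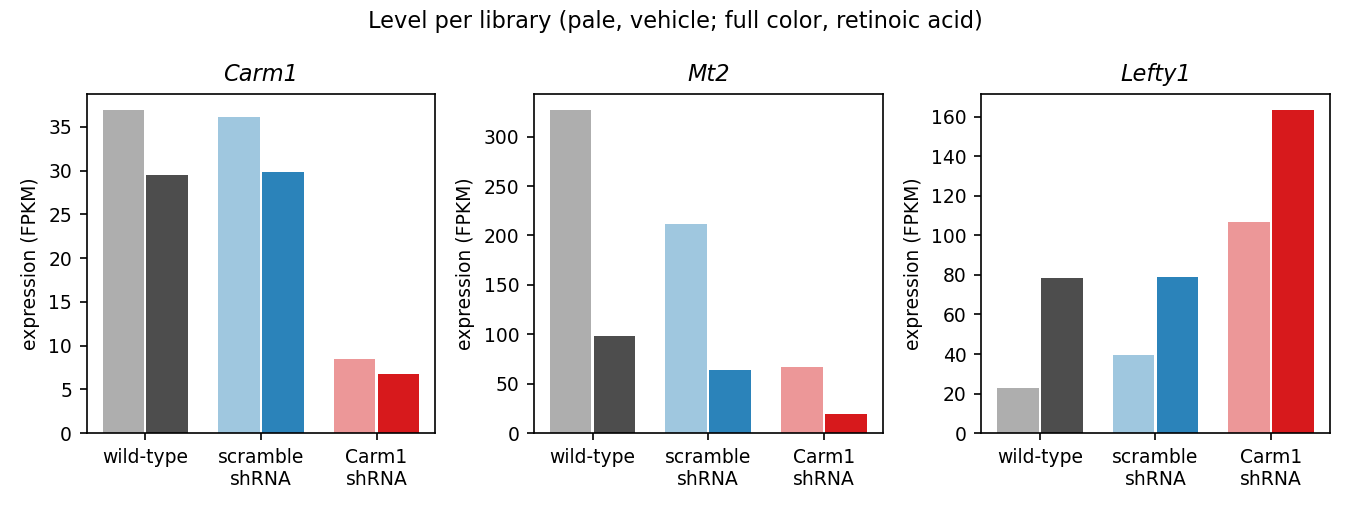
Expression in FPKM (vertical axes) of Carm1, Mt2 and Lefty1 in the 3 lines; each bar is 1 library, pale with vehicle and full color with RA, and the axes start at 0. Carm1 was 8.49 and 6.73 FPKM in the Carm1 shRNA line against 29.5 to 37.0 FPKM in the control lines.

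RA changed the expression of many genes in all 3 lines. The 12 highest-ranked genes that rose included Cyp26a1, which encodes an enzyme that degrades RA, together with the Hox genes Hoxb2, Hoxa5, Hoxb1, Hoxb6, Hoxb8 and Hoxa3, the RA-binding protein gene Crabp2, the retinol transporter gene Stra6, Zfp703 and the crystallin gene Crygc. Cyp26a1 (chromosome 19, 37772298 to 37776026) rose from 0.133, 0.258 and 0.158 FPKM to 111, 235 and 185 FPKM in the wild-type, scramble and Carm1 shRNA lines (log2 change 7.17 ± 0.18 SE, limma adjusted p = 0.000134). The genes that fell furthest in every line included Tdh, the threonine dehydrogenase of mouse stem cells, which went from 373, 338 and 329 FPKM to 40.9, 26.4 and 35.8 FPKM (log2 -3.32 ± 0.11). Enox1 (-2.74 ± 0.07), the acetylcholine receptor subunit gene Chrna9 (-2.50 ± 0.08), the cadherin gene Cdh3 (-2.51 ± 0.18), the growth factor gene Fgf17 (-2.03 ± 0.08), N4bp3, Nphs1, Kirrel2, Pdzd4, Tcea3 and Pcolce2 also fell.

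In the limma fit with the line as block, 4816 genes were higher and 2325 lower with RA among 11227 tested, and 586 rose and 90 fell at least 2-fold in each of the 3 lines. The total of 7141 was 4795 without the scramble line and 5442 without the Carm1 shRNA line, and 5344 of 20460 genes passed without a filter. The median change of all genes was 0.14 (log2), against 0.0015 after median-of-ratios scaling and -0.05 after quantile normalization. Higher genes made up 67.4% of the calls as deposited, 50.2% after median-of-ratios scaling and 43.8% after quantile normalization. The wild-type line responded least by size, with 698 genes induced and 138 repressed at least 2-fold, against 1280 and 212 in the scramble line and 1065 and 200 in the Carm1 shRNA line. Without the wild-type line, 1082 genes changed at least 2-fold in both remaining lines, against 676 in all 3.

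Most of the measured Hox genes, which encode the transcription factors of head-to-tail patterning, rose. Of 22 members that reached a mean of 1 FPKM 21 rose and 0 fell, all 21 at least 2-fold in every line, with a median log2 change of 3.01; 21 rose when adjusted over the list alone. Hoxb1 went from at most 0.0301 FPKM to 29.3, 53.3 and 23.2 FPKM in the wild-type, scramble and Carm1 shRNA lines. Hoxa11 was the exception (log2 -0.01 ± 0.06, limma adjusted p = 0.875). The other 17 listed Hox genes lay under that mean and were not tested; 8 of them were higher and 5 lower with RA in all 3 lines. A gene near 0 with vehicle reaches the mean only if RA raises it, so the share of 21 in 22 does not extend to the whole list. Genes of retinoid metabolism, transport and reception behaved alike, with 21 of 25 higher and 2 lower. The same limit holds for this list, as 8 members were not tested, 4 of them higher and 1 lower with RA in all 3 lines. The receptor gene Rarb rose by 3.39 ± 0.11, the retinaldehyde reductase gene Dhrs3 by 3.39 ± 0.14 and the germ cell gene Stra8 by 4.64 ± 0.32. Rarg (-0.33 ± 0.08) and Crabp1 (-0.52 ± 0.10) fell. The camera adjusted p was 7.04e-08 for the Hox list and 0.000538 for the retinoid list, and adjusted p = 0.522 for both with an estimated correlation. The estimated form tests at 2 residual degrees of freedom, here and for the lists below, so its larger p-values do not measure gene correlation alone.

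Genes of naive and general pluripotency were mostly lower with RA. Of 34 measured members 23 fell and 4 rose, with the same counts when adjusted over the list alone. Utf1, a chromatin factor of undifferentiated cells, fell from 324, 336 and 356 FPKM to 101, 52.6 and 80.9 FPKM in the wild-type, scramble and Carm1 shRNA lines. Pou5f1, the core pluripotency factor Oct4, fell by 0.94 ± 0.15, and Zfp42 (-0.95 ± 0.13) and Tet1 (-1.61 ± 0.13) fell too. Nanog did not pass the test (0.07 ± 0.12, limma adjusted p = 0.602). The 4 members that rose were Tbx3 (0.76 ± 0.08), Spp1 (1.41 ± 0.10), the Nodal antagonist gene Lefty1 (1.11 ± 0.21) and the E-cadherin gene Cdh1 (0.76 ± 0.15). The list's camera adjusted p was 6.59e-07, and adjusted p = 0.567 with an estimated correlation.

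All 14 measured genes of extraembryonic endoderm, the yolk sac lineage, rose. Col4a1 went from 11.6, 11.7 and 11.0 FPKM to 73.0, 69.2 and 64.2 FPKM, Col4a2 rose by 2.63 ± 0.07, and the transcription factor gene Gata6 rose by 2.56 ± 0.06. A further 12 members lay under the mean of 1 FPKM and were not tested, 7 of them higher and 2 lower with RA in all 3 lines. Proliferation genes were lower, 17 of 26 measured falling and 3 rising. Among them were Mycn (-1.92 ± 0.19), Myc (-1.54 ± 0.07), Ccnd1 (-1.14 ± 0.09) and Ccne1 (-1.08 ± 0.11). The members that rose, Cdkn1b (0.61 ± 0.09), Cdkn1c (1.58 ± 0.26) and Cdkn2a (1.03 ± 0.11), encode inhibitors of the cell cycle. The camera adjusted p was 1.88e-05 for each of these lists, with adjusted p = 0.522 and 0.625 under an estimated correlation. All 14 and all 20 changed members also passed when adjusted over the list alone.

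Further lists passed camera at the preset correlation with larger adjusted p-values. Of 21 measured glycolysis and hypoxia genes 11 fell and 5 rose (adjusted p = 0.00522). Pdk1, which restrains pyruvate oxidation, fell by 1.90 ± 0.13, and Eno1 fell by 0.73 ± 0.06, whereas the glucose transporter genes Slc2a1 (0.99 ± 0.23) and Slc2a3 (0.75 ± 0.11) and Vegfa (1.30 ± 0.08) rose. Of 22 LIF, BMP and WNT targets 10 fell and 4 rose (adjusted p = 0.0196). Egr1 fell by 1.92 ± 0.17 and Spry4 fell by 1.73 ± 0.17, whereas Id1 (0.95 ± 0.13), Id2 (2.63 ± 0.17), Smad6 (2.02 ± 0.21) and Cdx1 (2.61 ± 0.10) rose. Of 15 imprinted genes 11 rose and 2 fell (adjusted p = 0.0375), led by Dlk1 (3.54 ± 0.35) and Sgce (2.66 ± 0.13). With an estimated correlation these lists gave adjusted p = 0.522, adjusted p = 0.567 and adjusted p = 0.522. The LIF, BMP and WNT call ended after median-of-ratios scaling (adjusted p = 0.0771) and after quantile normalization (adjusted p = 0.277), and the glycolysis call after quantile normalization (adjusted p = 0.153). The counts adjusted over the list alone were equal to those above except 12 imprinted genes higher.

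The other 10 lists did not pass. In the neural list 8 of 16 members rose, among them Gap43 (1.94 ± 0.10), Nes (1.43 ± 0.11) and Pax6 (1.29 ± 0.22), and 3 fell, Tubb3, Stmn2 and Elavl3 (adjusted p = 0.528). In the formative pluripotency list 4 rose and 5 fell of 13 (adjusted p = 0.558), including Sall2 (2.14 ± 0.10) and Fgf15, which fell by 1.65. Of 7 trophoblast and keratin genes 5 rose and 1 fell (adjusted p = 0.55), Krt18 by 2.16 ± 0.24. Of 8 fibroblast and feeder markers 6 rose and 1 fell (adjusted p = 0.198). Col1a1 and Col1a2, the abundant fibroblast collagens, did not exceed 3.05 and 3.75 FPKM in any library. Of 11 arginine methyltransferases 3 rose and 4 fell (adjusted p = 0.0529; 3 and 7 over the list alone). Prmt2 rose by 1.32 ± 0.15 and Prmt8 by 1.17 ± 0.14, and Prmt5 fell by 0.63 ± 0.07. The coregulator list (5 rose, 2 fell of 19), the p53 and stress list (5 and 7 of 20), the interferon list (2 and 2 of 6), the mesendoderm list (2 and 1 of 5) and the two-cell-like list (0 and 1 of 1) had adjusted p = 0.955, 0.128, 0.558, 0.69 and 0.186. Untested members under the mean of 1 FPKM numbered 14, 16 and 14 in the interferon, mesendoderm and two-cell-like lists. Of these 10, 9 and 8 were higher and 0, 3 and 0 lower with RA in all 3 lines. Adjusted over the list alone the counts differed only for the neural list (9 rose, 3 fell) and the formative list (5 and 6), besides the methyltransferases. The p53 and stress list passed without the Carm1 shRNA line (adjusted p = 0.0466). Camera pointed down while the median was above 0 for the formative, coregulator and interferon lists, and while the mean was above 0 for the formative, coregulator, methyltransferase and mesendoderm lists. The medians of the formative (0.14) and coregulator (0.12) lists fell below 0 under both other scalings, and that of the interferon list (0.18) under quantile normalization. That of the mesendoderm list (-0.02) was above 0 without the scramble or the Carm1 shRNA line.

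With vehicle, the Carm1 shRNA line was set against both control lines to show differences present before RA. Lefty1 (chromosome 1, 182865170 to 182868532) was 107 FPKM in the Carm1 shRNA line against 39.3 FPKM in the scramble and 22.8 FPKM in the wild-type line. Lefty2, its near copy, was 122 FPKM against 52.9 and 28.6 FPKM; their reads can be split by the counting, so both levels are uncertain. The BMP target Id2 was 34.0 FPKM against 14.3 and 7.40 FPKM, and the cyclin gene Ccnd2 was 26.2 FPKM against 7.59 and 12.1 FPKM. Bcl11a, Crmp1, Ppp1r14a, Lhx6 and Soga3 were likewise at least 2-fold higher than in both controls. Stra8, a gene of meiotic entry, was 4.29 FPKM against 32.8 FPKM in the scramble and 23.4 FPKM in the wild-type line. The metallothionein genes Mt2 (67.2 FPKM against 212 and 327 FPKM) and Mt1 (24.4 FPKM against 62.9 and 140 FPKM), the germ cell gene Dmrt1 (7.12 FPKM against 25.1 and 22.4 FPKM), Slc9b1, Vax2, Yipf2 and Eif2s3y were lower too.

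These genes were picked by size. A limma contrast with the mean of the control lines was added after the data were examined. It called Eif2s3y (log2 difference -3.13), Stra8 (-2.44), Carm1 (-1.98) and Mt2 (-1.95) lower in the Carm1 shRNA line. These calls are no evidence about replicate cultures, since each treatment had 1 Carm1 shRNA library. The error is only the spread between the RA responses of the control lines, at 1 residual degree of freedom. No p-value or count of genes is therefore given. With the wild-type line in that place the contrast called more genes under either treatment, and with the scramble line fewer. The lines on the other side then include the Carm1 shRNA line, as in the counts by size. Eif2s3y also differed between the controls, with the scramble line at -3.90 ± 0.08 from the wild-type line (limma over both treatments, adjusted p = 0.000391). So did Mt2, at -0.62 ± 0.08 (same limma fit, adjusted p = 0.0356). By size, 10 genes were at least 2-fold higher and 9 lower than in both controls; with the scramble line in that place the count was 2, and with the wild-type line 68. Against the scramble line alone 33 genes differed and against the wild-type line alone 147. Lists whose median lay in the outer 2.5% of random lists against both controls numbered 4, all higher: naive pluripotency (median log2 difference 0.09 from scramble and 0.14 from wild-type), glycolysis (0.11 and 0.20), LIF, BMP and WNT targets (0.19 and 0.31) and imprinted genes (0.14 and 0.35). Since both differences share the Carm1 shRNA library, part of this agreement may come from that library, and the scramble and wild-type lines in its place gave 2 and 3 lists.

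With RA, the Carm1 shRNA line was set against both control lines in the same way. Foxd3, a factor of pluripotent and neural crest cells, was 9.74 FPKM against 2.75 FPKM in the scramble and 3.18 FPKM in the wild-type line. Fgf4, a growth factor of pluripotent cells, was 46.4 FPKM against 18.6 and 15.8 FPKM, Cdh3 was 7.38 FPKM against 2.32 and 2.38 FPKM, Lgals3 was 9.86 FPKM against 2.31 and 2.22 FPKM, and Pou4f2 was 8.83 FPKM against 1.90 and 2.25 FPKM. The endoderm regulator Hnf4a was 5.18 FPKM against 1.60 and 0.559 FPKM, and Akr1c18, R3hdml, Igfbp7 and Sct were also higher. Cyp26b1 (chromosome 6, 84521408 to 84543902), another RA-degrading enzyme, reached 2.29 FPKM against 15.2 and 11.3 FPKM. The complement gene C3 was 0.205 FPKM against 2.89 and 6.05 FPKM, Dusp4 was 3.05 FPKM against 9.34 and 10.1 FPKM, and Mt1 was 9.78 FPKM against 47.5 and 45.7 FPKM. Mt2, Dmrt1, Arrdc2, the mesoderm gene Meox1 and Slc9b1 were lower as well.

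With RA the limma contrast with the mean of the control lines called Eif2s3y (log2 difference -3.06), Carm1 (-1.99) and Mt2 (-2.01) lower in the Carm1 shRNA line. It has the same limit as with vehicle, 1 Carm1 shRNA library and an error from the control lines alone. By size, 19 genes were higher and 16 lower than in both controls with RA; the scramble line in that place gave 8 genes and the wild-type line 97. Against the scramble line alone 68 genes differed, and against the wild-type line alone 253. Calls shared with the vehicle comparison were 1 higher gene, Lefty1, and 6 lower genes, namely Carm1, Mt2, Dmrt1, Mt1, Slc9b1 and Eif2s3y, where independent lists would share 0.0169 and 0.0128. Both comparisons use the same lines, so any lasting difference between lines recurs, and the excess is no sign of a Carm1 effect. In the limma contrast of the Carm1 shRNA and scramble lines over both treatments, 2 genes passed, Carm1 and Mt2 (-1.67 ± 0.08, adjusted p = 0.0132), and 1188 had an unadjusted p under 0.05. The count of genes that passed was 0 without a filter on low values and 0 after quantile normalization, so both calls ended there. It was 9 at a mean of at least 5 FPKM, 22 with limma's trend and 13 without the wild-type line. The contrast compares these lines only, because the vehicle and RA libraries of a line are not replicate cultures.

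The Hox list stood lowest among the lists in the Carm1 shRNA line with RA. Its median was 0.62 lower than in the scramble line (-0.62) and 0.46 lower than in the wild-type line (-0.46). Each difference lay at percentile 0 of 10000 matched random lists. These were matched on mean expression only and drawn as independent genes, so they do not share the RA response of Hox genes. Lists of genes that respond together can leave their range whenever lines differ in RA response. Between the control lines with RA (scramble minus wild-type), the retinoid list lay at percentile 99.99 and the Hox list at 77.8. In the Carm1 shRNA line, 19 of 22 Hox members were lower than in both controls. None of them was lower by 2-fold on the log2(FPKM + 1) scale, which understates differences of low genes such as Hoxc4. Hoxb1 was 23.2 FPKM against 53.3 and 29.3 FPKM, Hoxc4 was 1.91 FPKM against 9.28 and 4.63 FPKM, Hoxb8 was 22.2 FPKM against 41.5 and 38.8 FPKM, and Hoxa3 lay between the controls at 42.2 FPKM. The naive pluripotency list was higher, by 0.52 and 0.20 (percentile 100 in both), with 21 of 34 members above both controls. Nanog was 595 FPKM against 370 and 434 FPKM, Dppa5a 1895 FPKM against 1222 and 1364 FPKM, and Tfcp2l1 137 FPKM against 92.2 and 70.3 FPKM. Glycolysis and hypoxia genes were 0.17 and 0.12 higher. The retinoid list was 0.18 lower than in the scramble line (-0.18, percentile 0.11) and near the wild-type line (-0.04, percentile 15.9); Crabp2 was 69.6 FPKM against 297 and 126 FPKM. Lists in the outer 2.5% against both other lines numbered 3 for the Carm1 shRNA line, 2 for the scramble line, where naive pluripotency was low and retinoid genes high, and 5 for the wild-type line. The scramble line lay 0.18 above the wild-type line for the Hox list and 0.19 below it (-0.19) for the pluripotency list.

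**Figure D2:**
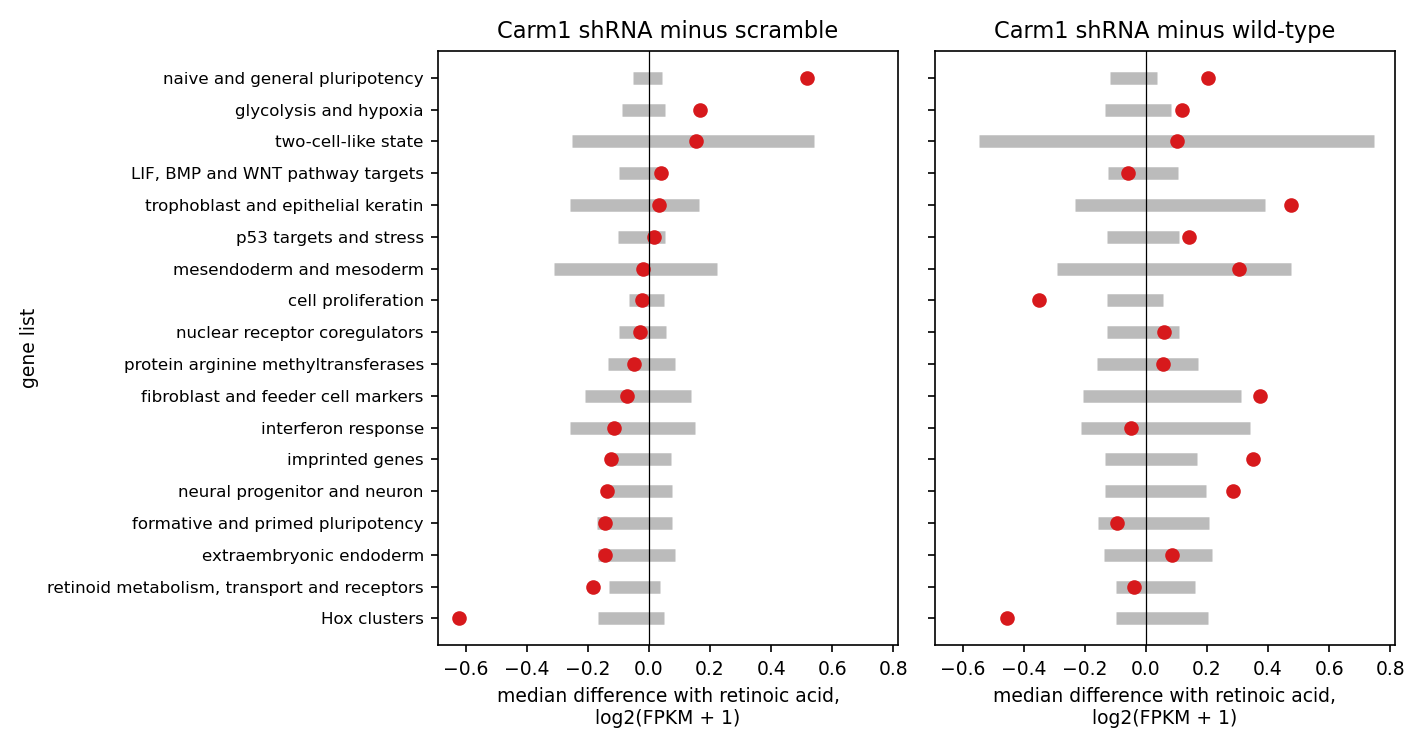
Median difference with RA of each gene list (vertical axis), on the log2(FPKM + 1) scale (horizontal axes), between the Carm1 shRNA line and the scramble (left) or wild-type line (right); gray bars span the central 95% of 10000 matched random lists. The Hox list lay at -0.62 and -0.46, and the naive pluripotency list at 0.52 and 0.20.

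The study's question, whether the RA response itself differed in the Carm1 shRNA line, was addressed gene by gene. Ccnd2 went from 26.2 to 12.4 FPKM in the Carm1 shRNA line, and from 7.59 to 15.8 FPKM in the scramble and 12.1 to 38.2 FPKM in the wild-type line. Arrdc2, the DNA repair glycosylase gene Tdg and Gpc3 were lower with RA in that line (log2 -0.75, -0.67 and -0.27) and higher in both controls. The responses of Cyp26b1 (1.69 against 3.98 and 3.62), C3 (0.27 against 1.93 and 2.79) and Tmem132e (1.19 against 2.28 and 2.27) were smaller than in the scramble and wild-type lines. Stra8 had the larger response (5.66 against 4.10 and 4.16), from a lower start to a lower end, 266 FPKM against 580 and 437 FPKM. Msx2 (3.39 against 2.21 and 1.07), Hnf4a, Akr1c18, Fmo1, Lbh, Rln1 and Prss35 also had responses at least 2-fold above both controls. So did Phlda2, which fell less (-0.87 against -2.13 and -2.47), and Fgf4, which did not fall (0.0045 against -1.03 and -1.33).

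In all, 10 genes had a higher and 7 a lower response by 2-fold than both controls, where the scramble line in that place gave 8 and the wild-type line 63. Against the scramble line alone the count was 45, and against the wild-type line alone 172. In simulated data the same count by size called 48 unchanged genes, more than the 17 counted here. The simulated noise came from the additive fit of these libraries and includes any real difference of response. The 48 may therefore be too high, and they do not settle whether the 17 exceed noise. The limma interaction test called 0 genes, with 409 at an unadjusted p under 0.05, and at 1 residual degree of freedom it recovered 0 of 100 simulated 4-fold differences of response. Its yardsticks called 0 genes as well, with 345 at an unadjusted p under 0.05 for the scramble and 1210 for the wild-type line. Lists with a median response in the outer 2.5% against both controls were the Hox list (-0.49 and -0.37), the formative pluripotency list (-0.24 and -0.48), LIF, BMP and WNT targets (-0.17 and -0.28) and, higher, the p53 and stress list (0.13 and 0.08); the scramble and wild-type lines in that place gave 3 and 4 lists. The naive pluripotency list was not among them, with a median response 0.32 above the scramble line (percentile 100) but -0.02 against the wild-type line (percentile 61.7), from which it had already differed by 0.14 with vehicle.

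Genes induced at least 2-fold in the wild-type line were used to compare the other lines, so that neither line compared made the choice. The choice may still favor the scramble line, which correlated more closely with the wild-type line than the Carm1 shRNA line did. The correlations were 0.9889 against 0.9861 with vehicle and 0.9818 against 0.9775 with RA. Among these 698 genes the median log2 response was 1.75 in the scramble and 1.64 in the Carm1 shRNA line, and 442 genes (63.3%, exact Clopper-Pearson 95% interval 59.6% to 66.9%, treating genes as independent, which they are not) had the smaller response in the Carm1 shRNA line. The median difference was -0.13, with quartiles of -0.38 and 0.13. Of 138 repressed genes, 84 (60.9%) fell less in the Carm1 shRNA line. Among 980 genes induced on the mean of the 3 lines the share with the smaller response than in the scramble line was 60.3%. Against the wild-type line the comparison was a different one: among 1280 genes induced in the scramble line, 24.0% had the smaller response in the Carm1 shRNA line, with medians of 1.30 in that line and 1.01 in the wild-type line. As a yardstick, the control lines were compared over the 1065 genes induced in the Carm1 shRNA line. The median difference, scramble minus wild-type, was 0.42, and 11.9% of these genes had the smaller response in the scramble line. The control lines thus differed by more than the -0.13 between the Carm1 shRNA and scramble lines. That smaller difference therefore cannot be told from an ordinary difference between lines.

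More genes passed the test between the control lines than between the Carm1 shRNA and scramble lines, except without a filter on low values, where both counts were 0. Mest, an imprinted gene, was 74.7 FPKM with vehicle in the wild-type line and 1.09 and 1.31 FPKM in the scramble and Carm1 shRNA lines. The immediate early gene Egr1 was 55.6 FPKM against 7.53 FPKM in each shRNA line. In limma, 201 genes differed between the scramble and wild-type lines (84 higher, 117 lower) and 638 between the Carm1 shRNA and wild-type lines, against 2 between the Carm1 shRNA and scramble lines. The count for the scramble and wild-type lines was 94 without the Carm1 shRNA libraries, and ranged from 64 at a pseudocount of 0.1 to 853 with limma's trend under the other alternatives that kept a filter.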

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

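The opposite sign itself was not tested for any gene in this part, and limma's interaction test of the response gave adjusted p = 1 for each of the 5 genes, so none passed, in a test that recovered 0 of 100 simulated 4-fold differences of response. The genes were picked by sign from the named genes whose RA response differed at least 2-fold from both control lines. Their response had 1 sign in the Carm1 shRNA line and the opposite sign in both control lines, each from 1 library per treatment. Genes with smaller differences were not searched. Ccnd2, a cyclin gene, had a log2 response of -1.02 in the Carm1 shRNA line, 0.96 in the scramble and 1.58 in the wild-type line. Arrdc2 had -0.75 against 1.41 and 0.64, from 8.05 to 4.39 FPKM. Tdg, the thymine DNA glycosylase gene, had -0.67 against 0.87 and 0.62, from 15.2 to 9.16 FPKM. Gpc3, a heparan sulfate proteoglycan gene, had -0.27 against 0.97 and 1.05. Fgf4 had 0.0045 against -1.03 and -1.33, so its sign in the Carm1 shRNA line rests on levels of 46.3 and 46.4 FPKM and amounts to no difference. No explanation was tested for these genes.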

How the results depend on the processing

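Keeping rows with a failed estimate and leaving out rows of low data were chosen after seeing the data; the other alternatives were planned. The count of RA-responsive genes (7141) stayed within 1.5 times under every alternative (4795 to 7385), at 5699 without the line as block, so fewer genes passed without the pairing by line, and 4795 to 6988 without 1 line each. Carm1 with RA stayed at 20.1% to 23.3% of the scramble level, and the 3 lists apart in the Carm1 shRNA line with RA numbered 3 or 4. Other results moved, and the cause was not tested except where stated. Genes changed 2-fold by RA in every line (676) were 1075 at a pseudocount of 0.1, 225 at 5, 395 at a mean of at least 5 FPKM, 1906 at 1.5-fold, and 707 to 1082 without 1 line each. The 2 genes between the Carm1 shRNA and scramble lines became 4 and 5 at pseudocounts of 0.5 and 5, 0 without a filter, 9 at a mean of at least 5 FPKM, 0 after quantile normalization, 22 with trend, and 13 without the wild-type line. The 201 genes between the scramble and wild-type lines became 64 and 478 at pseudocounts of 0.1 and 5, 0 without a filter, 420 at a mean of at least 5 FPKM, 91 after quantile normalization, 853 with trend and 94 without the Carm1 shRNA line. Counts against both controls, which a lower pseudocount raises by construction for low genes, were with RA (35) 72, 55 and 10 at pseudocounts of 0.1, 0.5 and 5, 23 at a mean of at least 5 FPKM, 210 at 1.5-fold, 68 against scramble only and 253 against wild-type only. With vehicle (19) they were 46 and 9 at pseudocounts of 0.1 and 5, 106 at 1.5-fold, 33 and 147 against scramble and wild-type only. For the RA response (17) they were 64, 26 and 2 at the 3 pseudocounts, 8 at a mean of at least 5 FPKM, 132 at 1.5-fold, 45 and 172 against scramble and wild-type only. The interaction count (0) was 1 with trend and 1 with failed rows kept, where Zmynd8 is listed at 0 in 2 libraries. The share of wild-type-induced genes with the smaller response in the Carm1 shRNA line (63.3%) was 57.1% after median-of-ratios scaling, 58.3% after quantile normalization and 60.3% for genes chosen on the mean of the 3 lines; the value of 24.0% for genes chosen in the scramble line also changed the reference to the wild-type line, so it compares other lines. The 8 RA lists became 0 with an estimated correlation and were 6 to 10 otherwise. That setting also tests at the 2 residual degrees of freedom, so the loss does not show that gene correlation undoes the lists. Glycolysis (estimated correlation 0.00552) and imprinted genes (-0.0267) lay below the preset 0.01 and were lost too. Under the other 2 scalings and without 1 line each, 86 single lists' calls stayed, 3 were lost and 1 was gained, and single lists' calls under the other alternatives were counted only as totals; of the lists' medians with RA against each control line 292 stayed and 68 moved; of the named genes' calls 869 stayed and 45 were lost, and 0 turned direction. Depth is known only as an estimate, which limits what the lowest values can show.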

Other observations

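The tests of the Hox list against each control line's overall response, of line differences and of feeder cells were chosen after the result was seen, as were the genes named in this paragraph. The wild-type line stood apart from both shRNA lines at least 2-fold in 68 genes with vehicle and 97 with RA, and 28 higher and 3 lower calls were shared, where independent lists would share 0.293 and 0.0268. The same lines enter both treatments, so the excess shows only that differences between lines lasted. Besides Mest and Egr1, Fabp3, a fatty acid carrier gene, was 168 FPKM with vehicle in the wild-type line against 49.4 and 34.8 FPKM in the scramble and Carm1 shRNA lines. The growth factor gene Fgf1 was 6.61 FPKM against 0.556 and 0.679 FPKM, and Pax2 was 4.12 FPKM against 0.552 and 0.785 FPKM, also with vehicle. With RA, the chromatin gene Hmga2 was 32.7 FPKM against 10.3 and 4.61 FPKM. The posterior Hox genes Hoxa10 (6.91 FPKM against 0.212 and 0.16 FPKM) and Hoxa11 (2.92 FPKM against 0.0745 and 0.0876 FPKM) were already present in the wild-type line with vehicle. The apoptosis gene Pmaip1 went the other way with vehicle, at 12.2 FPKM against 48.4 and 37.2 FPKM. Amd1 was 14.6 FPKM with vehicle against 0.0623 and 0.0453 FPKM; it has near-identical copies among which reads can be split, so this level is uncertain.

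Lower Hox expression with RA in the Carm1 shRNA line (19 of 22 genes below both controls) was set against technical and biological explanations. With vehicle the list's median difference was already -0.17 from the wild-type line (percentile 0.32 of matched random lists). It was -0.04 from the scramble line (percentile 2.88). Other scalings of the libraries left the median Hox difference at -0.45 or further from 0 against both controls, which argues against scaling. A smaller overall response does not account for the difference from the wild-type line, since over 959 induced genes outside the list the Carm1 shRNA line responded more (slope 1.16) and the scaled median Hox difference was -0.82 (resampling interval -1.11 to -0.239). Against the scramble line (slope 0.935) the scaled difference was -0.28 (interval -0.386 to -0.0762), too wide to settle that explanation. After scaling, 16 of 22 members lay below 0 against each control. Both intervals resample the Hox genes as if independent, which they are not, and hold no spread between cultures. An effect of Carm1 loss and a difference between lines cannot be told apart, because each shRNA was represented by 1 line. The scramble line lay 0.18 above the wild-type line, at percentile 77.8 of matched random lists. That is smaller in size than the Carm1 shRNA differences (-0.62 and -0.46), but it does not exclude a difference between lines.

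The distance of the wild-type line may reflect its chromosomes, its culture or drift between lines. Y-linked Eif2s3y was 35.8 FPKM with RA in the wild-type line and 0.132 FPKM in the Carm1 shRNA line, and 1.67 FPKM with vehicle in the scramble line, Ddx3y was 5.55 FPKM with vehicle, listed at 0 in the scramble and 0.0169 FPKM in the Carm1 shRNA line, and Kdm5d was listed at 0 in all 6 libraries. This is consistent with loss of the Y chromosome in most cells of the shRNA lines, and whether that loss accounts for the other genes stays open. The share of the 68 genes apart with vehicle that lie on the Y chromosome was 2.94%, but only 2 Y-linked genes were among the genes tested, so the share was bound to stay under the 50% set beforehand and decides nothing. For fibroblasts or feeder cells in the wild-type culture, the median of their markers with RA differed from the scramble line by -0.52. That value cannot decide, because these markers rose with RA and least in the wild-type line (list median 0.69 against 1.49 in scramble). With vehicle the median differed by 0.12. Col1a1 with vehicle was 0.221 FPKM, against 0.204 and 0.251 FPKM in the scramble and Carm1 shRNA lines. Col1a2 with vehicle was 0.0287 FPKM against 0.0079 and 0.0298 FPKM, and Col3a1 was 0.0232 FPKM and listed at 0 in both shRNA lines. At levels this near 0 the order of the lines decides nothing about such cells. An effect of the shRNA constructs and drift between lines stay open, untested.

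Metallothioneins Mt1 and Mt2 were lower in the Carm1 shRNA line under both treatments. Mt2 also differed between the control lines, with the scramble line at -0.62 ± 0.08 from the wild-type line (limma over both treatments, adjusted p = 0.0356). Less metal in that culture could lower them, but Slc30a1, another gene induced by metal, was not lower: the smallest ratio of a control to the Carm1 shRNA line was 0.76 and the largest 0.869 with vehicle and 0.932 with RA. The bound set beforehand asked for closeness to both controls in either direction, and the wild-type vehicle comparison lay outside it (1.32-fold higher in the Carm1 shRNA line), on the side opposite to that explanation. An effect of Carm1 loss and a difference between lines stay open.

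Splitting the 6 libraries into 3 and 3 in all 10 ways, the real split gave 7141 genes and the highest other split gave 0, so 1 of 10 splits reached the real count. For the camera count of lists, the real split gave 8 and the highest other split also 8, so 4 of 10 splits gave as many. With 10 splits the share cannot go under 0.1, which is too few to reach 0.05. Of the splits that part all 3 line pairs, the other 3 gave 0 genes and 3, 4 and 8 lists. These counts do not measure chance, because the line stays the block in every split. A split that parts only 1 line pair estimates the RA response of that line alone. The other 3 splits that part all pairs reverse RA in 1 line against the rest. The RA response thus enters their estimate or their residual, so neither 0 genes nor 8 lists there bears on chance.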
